A study of Mus musculus with 6 samples.

How the data were processed

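Gene expression was measured by RNA sequencing of total RNA from the habenula, a small epithalamic brain region, of C57BL/6 mice aged 2 months. The labels divide 6 libraries into 3 wild-type (WT) and 3 Tet2 conditional knockout (Tet2 cKO) libraries. Tet2 encodes a dioxygenase that oxidises 5-methylcytosine in DNA. The driver of the deletion, the deleted exons, and whether each library came from a separate animal are not given in the sources used here, so p-values measure the spread between these libraries.

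The deposited table holds raw counts for 55359 Ensembl genes in each library, per the file headers and the values, which are whole numbers. It also holds FPKM values made by the authors. These equal the deposited count per kilobase of exonic gene size, scaled by the library total, within 0.0051, for 100% of values in each of the 6 libraries. Per the submitters' processing notes, FastQC 0.10.1, cutadapt 1.9.1, HISAT2 2.0.1 and SAMtools 0.1.19 were used with build mm10. The read counter, the annotation release and the strand setting are not given in the sources used here, so reads of a gene and of a gene overlapping it on the opposite strand cannot be told apart. Genes with many near-identical copies can lose reads in counting. Gapdh, for example, stood at 4.78 ± 0.346 FPKM in WT (SD, n = 3). A low level was not general, since Actb, Rplp0, Eef1a1 and Rpl4 stood at means of 196, 96.3, 833 and 193 FPKM in WT. Levels of such genes are uncertain.

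Of 52083 gene identifiers shared with GENCODE mouse release 21 (GRCm38), 51516 had the same chromosome and width in the deposited table, but only 1494 had the same start and end. The table's coordinates therefore belong to another assembly and are not printed. Positions given are those of GENCODE release 21 on GRCm38, joined by gene identifier.

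The test fixed before the data were examined was limma on log2(FPKM + 1), with edgeR to be used if the table held counts. Since it did, the main test was edgeR 4.0.16 (quasi-likelihood, TMM normalisation, two-sided, Tet2 cKO minus WT, no covariate) in R 4.3.3, and limma 3.58.1 was run as an alternative. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 14539 in all, which held at least 99.1% of the counts of each library. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and intervals are 95% intervals. Library totals lay between 16089676 and 17917987 counts, and the common biological coefficient of variation was 10.4%. The standard error of the log2 difference had quartiles of 0.0858 and 0.165 over the tested genes. Intervals and limits made from counts alone cover counting error only.

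Before the data were examined, 40 gene lists were fixed, 17 of cell type or region markers and 23 of gene groups. The 39 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, on the edgeR counts and design. Alternatives were camera with the correlation estimated for each list, and fry. The list of pineal gland and subcommissural organ markers had 1 tested member, Sspo, and was not tested. A marker score per library was the mean of log2(FPKM + 1) over members, compared by an exact permutation test, which cannot give a p below 0.1 with 3 libraries against 3. The enrichment test of gene ontology terms was not run, because no gene passed in either direction. Camera over the table's own gene ontology terms with 10 to 500 tested genes was added after the data were seen.

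The rule for named genes was fixed in advance. It takes Tet2, Tet1 and Tet3, then 12 genes per direction whose groups do not overlap, filled by smallest unadjusted p where too few pass. It leaves out predicted genes, clones and pseudogenes. It adds 4 members of each list past the threshold and up to 2 of any other list described. The values of 1 gene named by the rule are not reported here. Which other lists to describe (medial, lateral and pan-habenula and thalamus neurons) was chosen after values were seen. Naming members of every list had been tried first and was dropped because many of those genes lie near 0 and change sign between settings. Any other gene named was chosen after its values were seen.

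Simulated counts with the means, library sizes and dispersions of these libraries, over 14539 genes of which 200 were changed, were used to test the method. The edgeR test recovered 34.3% of genes changed 1.49-fold, 85.1% of those changed 2-fold and 100% of those changed 4-fold. Of its 160 calls, 8.75% were false, above the nominal 5%. With the choroid plexus list moved by -0.5 on the log2 scale, camera gave adjusted p = 8.6e-21 with the preset correlation. With an estimated correlation it gave adjusted p = 0.0595. The preset also called 1 of 38 unmoved lists. Each gene was drawn independently, so the simulation held no correlation between genes. In the real libraries the choroid plexus list had an estimated correlation of 0.83. The simulated rates therefore do not carry over to genes that move together.

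Alternatives fixed in advance were other pseudocounts, filters, scalings and limma settings, a block for the replicate number, a fold minimum of 1.5, and leaving out each library. DESeq2 1.42.0, its size factors within edgeR, library totals, the filter filterByExpr, a length and GC correction, limma on log2(FPKM + 1) as such and the choroid plexus score as a covariate were added after the data were seen. Transcript GC was known for 99.1% of tested genes. The pseudocount, scaling and limma settings replace edgeR by limma as well as changing the named setting.

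Lists of liver and motile cilium genes were written after values had been seen. Some of their members had already stood out in these libraries, so each was also tested without those picked by hand or by that signal. After a first look at the outcomes, 3 tests of explanations were redefined. The cilium test moved from the hand-written list to whole gene families, then to the family members outside that list, with p-values adjusted over the 5 cilium gene sets tried and a margin of the standard error of the median, and the liver test to genes that had not first shown the signal, with a lower minimum count. The test for a single deciding library gained a margin of 1 SD. Explanations for the mitochondrial and immediate early lists were set aside before any test of them. Figures were drawn with matplotlib.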

Results

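The data are RNA-seq counts from the mouse habenula in 3 WT libraries and 3 libraries labelled Tet2 cKO. Library totals were 17297105, 16089676 and 17743639 counts in WT and 17441429, 17917987 and 17882130 counts in the libraries labelled Tet2 cKO. Mitochondrial genes took 6.33%, 6.25% and 7.66% of the counts in WT and 6.44%, 6.10% and 5.43% under the Tet2 cKO label. WT replicate 3 stood apart from the rest. It scored 30.4 on the first principal component, which held 34.5% of the variance, while the other 5 libraries lay between -14.8 and 8.12. Genotype accounted for 3.21% of that component and for 84.0% of the third, which held 17.4% of the variance. Any division into 3 and 3 has to fall on some component, and no other division was compared on them. The pan-habenula marker score of WT replicate 3 was 3.65, against 4.28 and 4.53 in WT replicates 1 and 2. Under the Tet2 cKO label it was 4.38, 4.02 and 4.33. WT replicate 3 also had the lowest medial and lateral habenula scores (3.44 and 3.68) and the highest score of GABAergic neurons (3.31). The cause was not tested. Pairs of libraries differed by a chi-square of 4.17 to 20.8 per gene, so no library was a copy of another.

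Tet2 was examined first, because it checks the labels. Its level was not lower in the libraries labelled Tet2 cKO. Tet2 (ENSMUSG00000040943, minus strand of chromosome 3, 133463679 to 133545139 on GRCm38) stood at 3.45, 3.46 and 3.71 FPKM in WT and at 4.47, 4.02 and 3.96 FPKM under the Tet2 cKO label. The log2 difference was 0.22 (95% interval 0.05 to 0.39), or 1.16-fold, and 3 of 3 libraries lay above every WT library. It did not pass the edgeR quasi-likelihood test (unadjusted p = 0.0174, Benjamini-Hochberg adjusted p = 0.9999), and the exact two-sided permutation test gave p = 0.1, the smallest it can give. The related dioxygenase genes Tet1 and Tet3 differed by -0.01 (SE 0.112) and 0.10 (SE 0.0961) on the log2 scale, and the sign for Tet1 changed with the processing. Leaving out each library gave 0.023 to 0.16 for Tet3. The count covers the whole gene, so reads of undeleted exons stay in it, and exons of Tet2 overlap the gene Gm42567 on the opposite strand. The whole-gene count thus neither shows a loss of Tet2 nor refutes the label. Every direction below is that of the libraries labelled Tet2 cKO, not of a shown loss of Tet2.

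**Figure D1:**
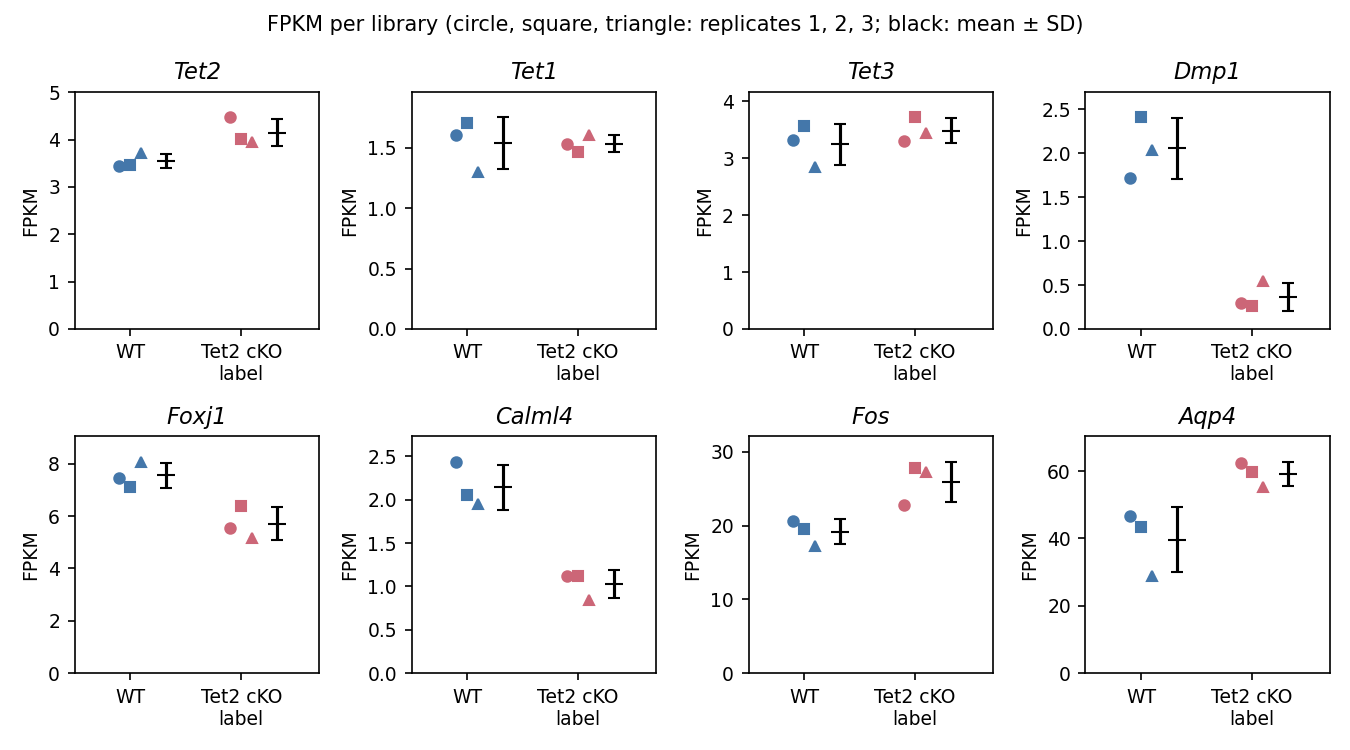
FPKM of 8 genes in each library, WT in blue and the libraries labelled Tet2 cKO in red, with the mean and SD of 3 libraries in black and replicates 1, 2 and 3 as circles, squares and triangles. Tet2 lies between 3.45 and 3.71 FPKM in WT and between 3.96 and 4.47 FPKM under the Tet2 cKO label.

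The comparison of libraries labelled Tet2 cKO with WT asks how deletion of Tet2 affects gene expression in the habenula. Choroid plexus and ependymal markers were lower as lists under the Tet2 cKO label, at a median of 0.437 and 0.742 times their WT level by camera with a preset correlation. These calls were lost with an estimated correlation (adjusted p = 0.412 and adjusted p = 0.244) and by fry (adjusted p = 0.995 and adjusted p = 0.394). Neuronal markers of the habenula did not pass, and no single gene did. The edgeR quasi-likelihood test called 0 of 14539 genes at a Benjamini-Hochberg adjusted p under 0.05, the smallest being adjusted p = 0.113. At an unadjusted p under 0.05 there were 374 genes (130 higher, 244 lower), against 727 that chance alone would give on average. That number depended on WT replicate 3. Without it there were 865 such genes, and limma with library weights gave 1036, both above 727. Other splits of the 6 libraries into 3 and 3 gave 244 to 1963 in the main test. Lying above 727 therefore does not show an effect of the label. Leaving out each other library gave 228 to 465. The groups did not overlap in 1028 genes, or 7.07%, where chance gives 10%. DESeq2 called 4 genes, namely Dmp1, Prelp and Calml4 lower and Igsf1 higher, and edgeR without a filter on low values called 49 (17 higher, 32 lower). Without WT replicate 3 the main test called 3 genes, and without WT replicate 2 it called 1.

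The smallest p belonged to Dmp1, which encodes an acidic phosphoprotein of bone and dentine matrix. Dmp1 (ENSMUSG00000029307, chromosome 5, 104202613 to 104214102 on GRCm38) stood at 2.06 ± 0.345 FPKM in WT and 0.367 ± 0.159 FPKM under the Tet2 cKO label (SD, n = 3 each), a log2 difference of -2.48 (SE 0.291). Prelp, a leucine-rich repeat proteoglycan of the extracellular matrix, differed by -0.72 (SE 0.115), and its exons overlap Gm15851 on the opposite strand. Calml4 differed by -1.07 (SE 0.182). The other genes with the smallest p among those lower were Cfap52, Ttc21a, Tmem267, Coch, Crb2, Lama5, Msx1, Tmem232 and Myo7a, with log2 differences from -0.92 (Msx1) to -0.36 (Myo7a). None of these 12 passed, and Cfap52, Tmem267 and Crb2 overlap other genes on the opposite strand.

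Among genes higher under the Tet2 cKO label, Igsf1, on the X chromosome, stood at 7.21 ± 1.34 FPKM in WT and 11.7 ± 0.140 FPKM under the Tet2 cKO label (SD, n = 3 each), a log2 difference of 0.69 (SE 0.119). Fabp7, a fatty acid binding protein of radial glia and astrocytes, differed by 0.50 (SE 0.0980), and Ddit4, a stress-induced inhibitor of mTORC1, by 0.50 (SE 0.113). Timp1, an inhibitor of metalloproteinases, differed by 1.46 (SE 0.347) at 0.737 FPKM in WT. Fos, Grp, H2-K1, Socs2, Aqp4, Npl and Rab34 followed, with log2 differences from 0.33 (H2-K1) to 0.70 (Npl). The microRNA gene Mir1943 had 0, 0 and 2 counts in WT and 6, 7 and 8 under the Tet2 cKO label. None of these 12 genes passed.

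Markers of the choroid plexus and of ependymal cells, which line the ventricles next to the habenula, were lower under the Tet2 cKO label. All 13 tested choroid plexus markers were lower, with a median log2 difference of -1.20 (camera adjusted p = 8.5e-23; adjusted p = 0.412 with an estimated correlation). No member passed over all genes and 6 passed when adjusted over the list alone, among them Calml4, Clic6, Folr1 and Otx2. Without a filter on low values, 10 of the 49 genes that edgeR called were choroid plexus markers, among them Calml4, Clic6 and Folr1. On the log2(FPKM + 1) scale, which understates changes of low genes, limma gave a median of -0.66. Clic6 stood at 13.4, 7.64 and 3.47 FPKM in WT and 5.04, 2.21 and 2.54 FPKM under the Tet2 cKO label, and 1 of the 13 genes had groups that did not overlap. The choroid plexus score was 3.22, 2.70 and 2.03 in WT and 2.40, 1.62 and 1.81 under the Tet2 cKO label, a range within WT of 1.19 against a difference between groups of -0.70. Without WT replicate 1 the median was -0.62 and Clic6 was at -0.77, against -1.34 with all libraries, and without Tet2 cKO replicate 1 it was -1.78.

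All 9 tested ependymal markers were lower, with a median of -0.43 (camera adjusted p = 7.3e-16; adjusted p = 0.244 with an estimated correlation). No member passed over all genes, 4 passed when adjusted over the list alone, and 6 had groups that did not overlap. Foxj1, the transcription factor of motile ciliogenesis, stood at 7.56 ± 0.481 FPKM in WT and 5.70 ± 0.628 FPKM under the Tet2 cKO label (SD, n = 3 each). Rarres2, Rsph1 and Ccdc153 differed by -0.52, -0.57 and -0.43, and exons of Rarres2 overlap Lrrc61 on the opposite strand. The ependymal score was 3.21, 3.24 and 3.40 in WT and 2.96, 2.97 and 2.83 under the Tet2 cKO label (exact permutation p = 0.1, adjusted p = 0.8 over the marker lists).

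Of 39 lists tested by camera with the preset correlation, 9 passed, 4 lower and 5 higher. None passed with an estimated correlation, and none by fry. In the simulation, camera with an estimated correlation also missed a list moved by -0.5 (adjusted p = 0.0595), and fry was not run there. Not passing either test is therefore no evidence that a list was unchanged. Mitochondrially encoded mRNAs were lower in 13 of 13 members, with a median of -0.18 (adjusted p = 6.5e-06; adjusted p = 0.718 with an estimated correlation). Examples were mt-Nd5, mt-Nd2, mt-Nd6 and mt-Cytb, at -0.25, -0.21, -0.19 and -0.18, and mt-Nd5 and mt-Nd6 overlap on opposite strands. Without Tet2 cKO replicate 3 the median was -0.10 and the adjusted p was 0.0884. Without WT replicate 3, which had the highest mitochondrial share, the median was -0.09, mt-Nd2 and mt-Cytb were at -0.14 and -0.088, and the adjusted p was 0.0167. Leaving out each library gave -0.29 to -0.13 for mt-Nd6. Quantile normalisation gave a median of -0.048. Heat shock and protein folding genes were lower in 16 of 17 members, with a median of -0.18 (adjusted p = 0.00826; adjusted p = 0.995 with an estimated correlation). Their direction rested on WT replicate 3, without which the median was 0.07 with adjusted p = 0.119, and without Tet2 cKO replicates 2 and 3 it was -0.11 each, with adjusted p = 0.00285 and adjusted p = 0.140. Pdia4, Hspa1b, Hsph1 and Hsp90b1 differed by -0.29, -0.65, -0.20 and -0.18, and without WT replicate 3 by -0.058, -0.23, -0.043 and -0.022.

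Immediate early genes, which neuronal activity induces, were higher in 8 of 12 members, with a median of 0.20 (adjusted p = 1.8e-05; adjusted p = 0.412 with an estimated correlation). Fos, Nr4a1, Egr1 and Dusp1 differed by 0.43, 0.35, 0.43 and 0.34, and 1 member, Fos, passed when adjusted over the list alone. Without WT replicate 3 the median was 0.08, with Egr1 at 0.25 and Dusp1 at 0.21, without WT replicate 2 it was 0.38, and without Tet2 cKO replicate 3 it was 0.13. Circadian clock genes were higher in 13 of 18 members, with a median of 0.10 (adjusted p = 0.00666; adjusted p = 0.718 with an estimated correlation). Ciart, Per2 and Per1 differed by 0.54, 0.20 and 0.31, and Npas2 by -0.35. Without WT replicate 3 the median was 0.03, Ciart and Per1 were at 0.34 and 0.15, and the adjusted p = 0.301, and without Tet2 cKO replicate 2 the adjusted p = 0.0773.

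Small differences were called for glia and antigen presentation. Myelin and mature oligodendrocyte markers were higher in 12 of 14 members, with a median of 0.07 (adjusted p = 0.0115; adjusted p = 0.859 with an estimated correlation), Mag, Mog and Mal differing by 0.11, 0.15 and 0.12. Astrocyte markers were higher in 9 of 12, with a median of 0.09 (adjusted p = 0.0233; adjusted p = 0.592 with an estimated correlation). The water channel gene Aqp4 differed by 0.57, Gja1 by 0.22, Ntsr2 by 0.15 and Sox9 by -0.26, and only Aqp4 passed when adjusted over the list alone. Major histocompatibility complex genes were higher in 5 of 6, with a median of 0.10 (adjusted p = 0.0233; adjusted p = 0.718 with an estimated correlation). H2-K1, H2-T23, B2m and H2-D1 differed by 0.33, 0.27, 0.09 and 0.04. Each of these 3 calls ended without single libraries. The adjusted p for myelin was 0.224 without WT replicate 2, 0.0626 without WT replicate 3 and 0.468 without Tet2 cKO replicate 1, and the median was 0.14 without WT replicate 1 and 0.050 without Tet2 cKO replicate 1. Mog and Mal were at 0.24 and 0.19 without WT replicate 1 and at 0.073 and 0.044 without WT replicate 3. For astrocytes it was 0.0726 and 0.0649 without WT replicates 2 and 3, and 0.0985 and 0.0884 without Tet2 cKO replicates 2 and 3. For histocompatibility genes it was 0.226 and 0.0626 without WT replicates 2 and 3, and 0.426 and 0.0999 without Tet2 cKO replicates 1 and 3. Their median was 0.15, 0.044 and 0.15 without WT replicates 1, 2 and 3, and 0.043, 0.26 and 0.062 without Tet2 cKO replicates 1, 2 and 3. Leaving out each library gave 0.16 to 0.37 for H2-T23, -0.031 to 0.21 for B2m and -0.032 to 0.14 for H2-D1.

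**Figure D2:**
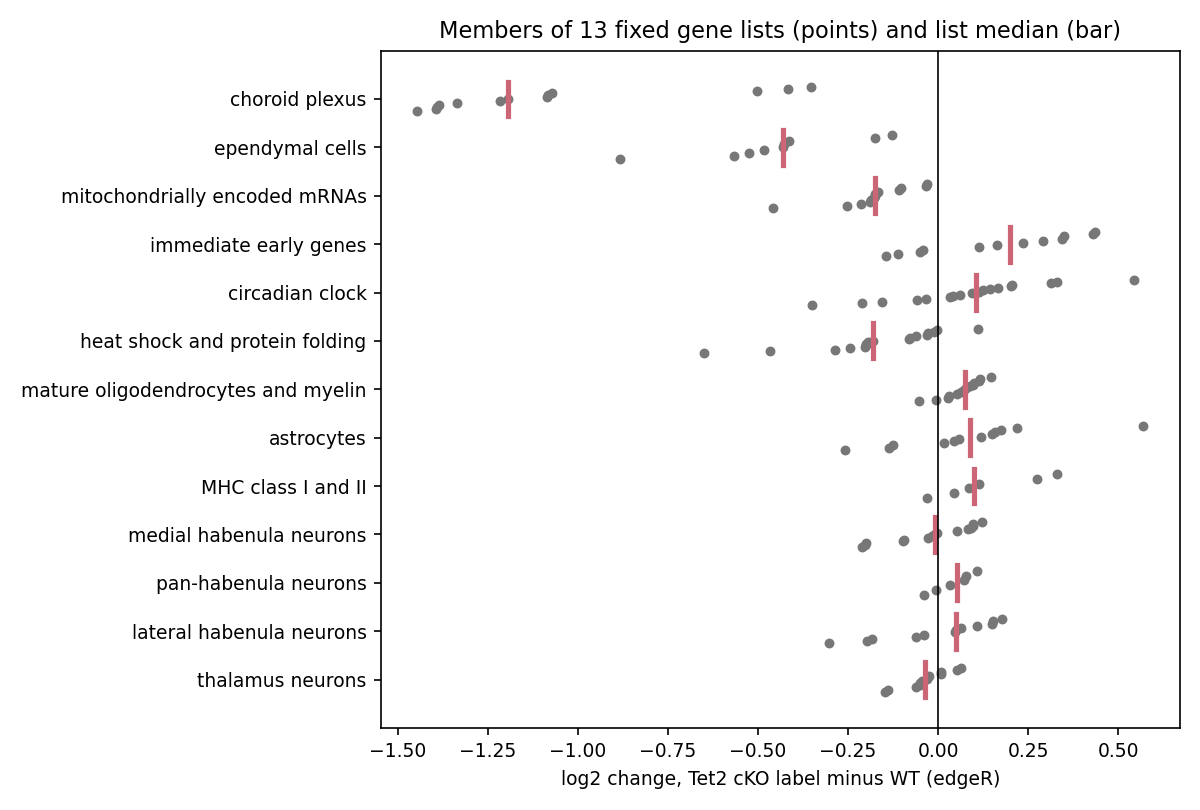
Log2 difference, libraries labelled Tet2 cKO minus WT, of each tested member (grey points) and the median (red bar) of the 9 lists past the camera threshold with the preset correlation and of 4 neuronal lists. The choroid plexus and ependymal members all lie below 0.

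Neuronal markers of the habenula did not pass. The median log2 difference was -0.01 for medial habenula neurons (15 tested), 0.05 for pan-habenula neurons (6 tested), 0.05 for lateral habenula neurons (12 tested) and -0.04 for thalamus neurons (12 tested). The camera adjusted p was 0.961, 0.520, 0.771 and 0.703. The pan-habenula score had a range within WT of 0.88 against a difference between groups of 0.087. For the medial habenula score these were 0.62 and 0.012. With that spread, not passing does not show that these neurons were unchanged. Calb2 stood at 304 ± 29.4 FPKM in WT and 266 ± 13.2 FPKM under the Tet2 cKO label (SD, n = 3 each), and Tac2 differed by 0.05 on the log2 scale. Gpr151, Nwd2, Gap43, Vgf, Tcf7l2 and Calb1 differed by 0.07, 0.03, 0.06, -0.20, -0.04 and 0.05, and all of these but Calb1 changed sign in some setting. Without WT replicate 3 Calb2 was at -0.12, and leaving out each library gave 0.0014 to 0.12 for Calb1. For lateral habenula neurons, oligodendrocyte precursors, imprinted genes, neuropeptides and synaptic vesicle genes, the median, mean and test were not all of 1 sign. Sspo, made by the subcommissural organ beside the habenula, stood at 0.49, 2.01 and 10.03 FPKM in WT and at 0.48, 6.36 and 0.50 FPKM under the Tet2 cKO label, a spread within each group larger than the difference between them.

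Below the expression filter, 15 genes had 0 counts in every WT library and at least 3 in each library labelled Tet2 cKO, against 1 gene (Gm9256) with the opposite pattern. The albumin gene Alb had 66, 73 and 65 counts under the Tet2 cKO label and 0 in each WT library. Against a limit of 3 counts over the WT group this is 65.3-fold after scaling by library totals. That value makes no allowance for counting error under the Tet2 cKO label. The others included the liver genes Serpina3k, Mup3, Fabp1, Gc and Ahsg, and also Serpinb2 and Ereg. These genes were named after their values were seen.

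**Figure D3:**
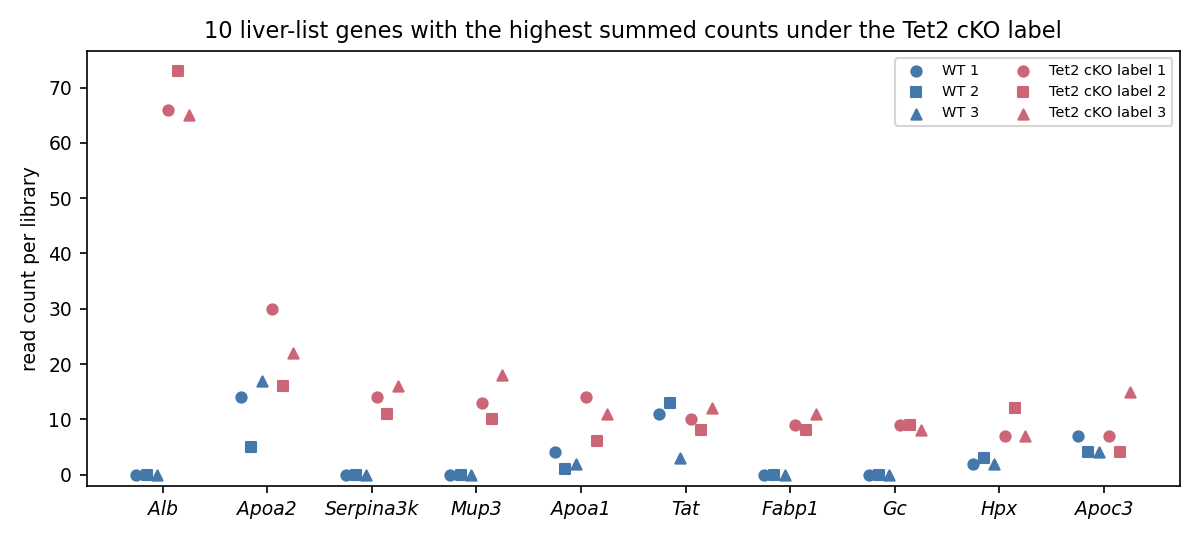
Read counts per library of the 10 genes of the liver list with the highest summed counts under the Tet2 cKO label, WT in blue and the libraries labelled Tet2 cKO in red. Alb has 65 to 73 counts in each library labelled Tet2 cKO and 0 in each WT library.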

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

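The tests of the liver genes were chosen only after the result was seen. In genes under the expression filter, a signal appeared under the Tet2 cKO label that was absent from WT, in 15 genes with 0 counts in each WT library. Alb alone had 204 counts over the 3 libraries labelled Tet2 cKO. A list of 28 liver genes had 748 counts under that label and 116 in WT, 6.19 times as many after scaling by library totals (95% interval 5.09 to 7.60), and all 28 genes were higher, of which 1 passed the expression filter. This ratio is inflated by selection, since 11 of the 28 genes are among those that first showed the signal. The other 17 genes had 297 counts against 116, or 2.46 times as many after scaling (95% interval 1.98 to 3.07), and 17 of 17 were higher. Some of these, such as Pck1 and Serpina1c, also had 0 counts in each WT library. Serpina1c and Mup20 belong to the families of Serpina1b and Mup3, which first showed the signal. The 17 genes are therefore not fully independent of the selection or of each other.

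Deeper sequencing is argued against, since the library totals differed by a factor of 1.04. A trace of liver RNA shared by the 3 libraries remains a candidate explanation that the tests do not settle. A single source should keep its genes in 1 set of proportions, and the simulated chi-square p for unequal proportions was 0.0193 and 0.137 among the 17 genes, and 0.149 and 0.413 over all list genes, with minimums of 5 and 10 summed counts. These tests decide nothing about such a source, since some of the 17 genes hold all 116 WT counts and may vary in these libraries at a level of their own, and Serpinb2 and Ereg, also at 0 in WT, are not liver genes. If the groups were handled apart, genotype and handling cannot be told apart in these libraries, and no biological explanation was tested.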

How the results depend on the processing

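The settings that the methods name as added were chosen after seeing the data. The higher Tet2 level kept its direction in all 21 alternatives, at 0.17 to 0.26, and passed adjustment in none.

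Genes called numbered 49 without a filter on low values (14 of them among the named genes), 2 (Dmp1, Alb) with filterByExpr and 4 with DESeq2. Leaving out each library gave 0 to 3 genes (Glt8d2 without WT replicate 2; Dmp1, Prelp and Ctxn3 without WT replicate 3). Every other alternative called 0 genes. The replicate block called 0, with 346 genes at an unadjusted p under 0.05 against 374 without it. Deviations from the group mean correlated at -0.04, 0.18 and -0.10 between same-numbered libraries. Between differently numbered libraries of the 2 groups they correlated at -0.20 to 0.19. These values show no sign of pairing by number, but cannot decide whether the libraries were paired. The cause of the differences in genes called was not tested.

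Lists called by camera numbered 5 with limma at a pseudocount of 0.1, 3 with quantile normalisation, 14 with the choroid plexus score as a covariate, 0 with an estimated correlation, 0 by fry, and 5 to 12 when leaving out each library. With a minimum mean of 5 FPKM, Tet2 and the choroid plexus and MHC lists left the test.

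The lower choroid plexus markers gave adjusted p = 0.412 in camera with an estimated correlation and adjusted p = 0.995 by fry. Their own score as a covariate removes their difference by construction (median 0.05, adjusted p = 0.842), which says nothing about the call. The median was -0.66 with limma on log2(FPKM + 1), -0.66 on rescaled FPKM and -0.68 with quantile normalisation. Leaving out each library gave adjusted p = 5.1e-46 to 3.3e-09. Like all leave-one-out values of lists here, these come from camera with the preset correlation. They do not carry the estimated correlation of this list, 0.83. The lower ependymal markers gave 0.244 with an estimated correlation and 0.394 by fry, and 5.9e-18 to 5.9e-08 when leaving out each library.

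Lower mitochondrial mRNAs were lost with quantile normalisation (median -0.048, adjusted p = 0.474), an estimated correlation (adjusted p = 0.718) and fry (adjusted p = 0.995), and ranged from 1.7e-07 to 0.0884 when leaving out each library. Higher immediate early genes were lost with limma library weights (adjusted p = 0.0541), an estimated correlation (0.412) and fry (0.995), and ranged from 5.7e-06 to 0.0379. Higher circadian clock genes were lost with limma at a pseudocount of 0.1 (adjusted p = 0.0569), on rescaled FPKM (0.0936), with quantile normalisation (0.0530), library weights (median 0.043, adjusted p = 0.387), an estimated correlation (0.718) and fry (0.995), and ranged from 0.000397 to 0.301 over the libraries left out. Lower heat shock genes were lost with limma at a pseudocount of 0.1 (adjusted p = 0.0569), quantile normalisation (0.0529), an estimated correlation (0.995) and fry (0.995), and ranged from 5.7e-06 to 0.140. Their median was -0.10 with limma on rescaled FPKM and -0.31 with the choroid plexus covariate. Their direction reversed with library weights (median 0.03, adjusted p = 0.971) and without WT replicate 3 (median 0.07, adjusted p = 0.119).

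Higher myelin markers were lost with quantile normalisation (adjusted p = 0.0529), library weights (median 0.021, adjusted p = 0.492), an estimated correlation (0.859) and fry (0.995), and ranged from 0.000484 to 0.468 over the libraries left out. Higher astrocyte markers were lost with limma at pseudocounts of 0.1 (adjusted p = 0.172), 0.5 (0.149) and 1 (0.125), rescaled FPKM (0.149), quantile normalisation (0.260), no trend (0.125), library weights (0.254), an estimated correlation (0.592) and fry (0.995), and ranged from 0.00501 to 0.0985. Higher MHC genes were lost without a filter on low values (median 0.061, adjusted p = 0.185), with filterByExpr (0.114), limma at pseudocounts of 0.1 (0.0631) and 0.5 (0.0555), quantile normalisation (0.0529), library weights (0.217), an estimated correlation (0.718) and fry (0.995), and ranged from 0.000386 to 0.426. With the choroid plexus covariate the median was 0.17 for myelin and 0.23 for MHC genes, and with a minimum mean of 5 FPKM it was 0.32 for immediate early genes.

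Tet1 changed sign with limma at pseudocounts of 0.1 (0.00474), 0.5 (0.00254) and 1 (0.00124), rescaled FPKM (0.0159), quantile normalisation (0.0111), no trend (0.00124) and the choroid plexus covariate (0.12). Quantile normalisation reversed mt-Nd6 (0.054), and the covariate reversed Gap43 (-0.092). Library weights reversed Tac2 (-0.16), Gpr151 (-0.040), Nwd2 (-0.12), Vgf (0.019) and Tcf7l2 (0.017). Leaving out each library gave log2 differences from -0.11 to 0.064 for Tet1, -0.035 to 0.23 for Gap43, -0.031 to 0.21 for B2m, -0.19 to 0.24 for Tac2, -0.16 to 0.35 for Gpr151, -0.27 to 0.30 for Nwd2, -0.32 to 0.050 for Vgf, -0.086 to 0.024 for Tcf7l2 and -0.032 to 0.14 for H2-D1.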

Other observations

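The tests of residual correlation, of Tet2, of a single library, of cilium genes and of gene ontology terms were chosen or given their bounds only after the result was seen, and the choroid plexus covariate was chosen after the data were seen. Cilium genes were examined beyond the fixed lists. A hand-written list of 61 motile cilium genes, partly chosen after its members stood out, was lower in 57 of 61, with a median log2 difference of -0.34 (camera adjusted p = 4.6e-41; adjusted p = 0.0704 with an estimated correlation). The tested members of the Dnah, Dnai, Cfap, Rsph, Drc and Tekt families outside the fixed lists were lower in 42 of 44 genes, with a median of -0.26 (adjusted p = 2.0e-26; adjusted p = 0.0799 with an estimated correlation), but 33 of these 44 are on the hand-written list. The other 11 family members were lower in 10 of 11, with a median of -0.077 (adjusted p = 0.00814; adjusted p = 0.225 with an estimated correlation). With the choroid plexus score as a covariate the medians were -0.56 for the hand-written list, -0.46 for the 44 family genes and -0.16 for the 11. Of the table's own annotation, the motile cilium term was lower in 8 of 17 genes (camera adjusted p = 0.396), and the broader cilium term was lower in 43 of 64, with a median of -0.04 (adjusted p = 0.00814; adjusted p = 0.0799 with an estimated correlation). Whether the ependymal decrease extends to other cilium genes stays open. No set passed with an estimated correlation, but that test also missed a planted change in the simulation. The hand-written list was partly chosen by the change itself, so the 11 genes left outside it decide nothing either.

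Choroid plexus and ependymal markers were both lower. Unequal amounts of choroid plexus in the dissected tissue are a candidate explanation for the choroid plexus part. Its members kept an estimated correlation of 0.83 within groups, and the score varied more within WT than between groups. Whether 1 library decides that decrease cannot be told from the test used. The median nearest to 0, without WT replicate 1, was -0.62, against -1.20 with all libraries. A loss of 50% of the log2 difference would give -0.60. The margin was the SD of 0.412 among the 6 fits, which an influential library itself widens, so the test could hardly decide. The tables argue against the ependymal decrease merely following choroid plexus, since its median was -0.56 with that score as a covariate. That fit rests on 6 libraries and covers only the amount of choroid plexus. Unequal amounts of ependymal tissue in the dissection were not tested. An effect of genotype on these cells stays open.

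Tet2 was not lower under the Tet2 cKO label. The tables argue against a loss of 50% or more of its reads in the dissected tissue, since the interval of the log2 difference ended at 0.39 and began above 0. A deletion that removes few reads of the gene cannot be told apart from no deletion, since only the whole-gene difference of 0.22 was used and no counts per exon. A deletion limited to a minor cell type and mislabelled libraries were not tested.

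Sequence around a targeted allele could differ between the groups. Of 67 tested genes within 10 Mb of Tet2, 5 (7.46%, exact 95% interval 2.47 to 16.6%) were at an unadjusted p under 0.05, against 2.55% of other genes (two-sided Fisher exact p = 0.0289). These 5, named after their values were seen, were Sgms2, Rpl34, Ddit4l, Pdlim5 and Col25a1. With so few genes, and none past adjustment, this is a hypothesis. Camera over 1731 gene ontology terms of the table called 0 with the preset correlation (smallest adjusted p = 0.0575, collagen trimer) and 0 with an estimated one.

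The 6 libraries can be split 10 ways into 3 and 3, too few for a share under 0.05. Genes past adjustment numbered 0 in the real split and at most 0 in the others, so 10 of 10 were as large. Genes at an unadjusted p under 0.05 numbered 374 in the real split and up to 1963 in another. With the real split included, 6 of 10 were as large, so the real split did not stand out. Lists past camera with the preset correlation numbered 9 in the real split and up to 15 in another, with 8 of 10 as large. Gene ontology terms with an estimated correlation numbered 0 in each, 10 of 10. The size of the ependymal median was 0.43 in the real split and at most 0.32 in the others, while the choroid plexus list had a smaller adjusted p in another split (6.6e-51 by camera).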
